A study of Homo sapiens with 24 samples.

How the data were processed

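The series holds 24 libraries of HOS cells with stable short hairpin RNAs, a control (shNC) and 2 hairpins against METTL1 (shM1-1 and shM1-2). Of these 12 are polysome profiling libraries, total RNA and polysome RNA from each population with n = 2, and 12 are TRAC-seq libraries, with and without cleavage, of RNA demethylated with AlkB, per the labels. Groups and replicate numbers came from the sample titles. Nothing states that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

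The submitters' processing notes name TopHat2, HTSeq, Bowtie2 and the builds hg38 and hg19, with no roles and no versions. Chromosome accessions in the deposited expression table are those of GRCh38, and coordinates are given as deposited. The expression table held 18275 gene lines; 580 continuation lines of annotation text were left out, and 2 lines were empty. The authors' deposited expression values name no unit and were read as FPKM. In the 8 libraries with matched counts, count divided by value gave 1 length per gene, and the factor per library followed the library total within a ratio of 0.998 to 1.005, as FPKM would. The deposited expected counts, of which 57.9% were whole numbers, matched the labels by column name for the 8 libraries of shNC and shM1-1 only. A further 4 count columns match no label by name and were not used. Log2 fold changes in the deposited table are the authors' own, and the q-values beside them come from DESeq2, per the file headers. The deposited TRAC-seq scores were read as log2 values from their range and from repeated values at exact log2 of small whole numbers. The formula of the score was not given in the sources used here, and each of its 6 columns stands for 1 cleaved and 1 uncleaved library. The score table held 27547 positions of 626 tRNA genes and gave no base. For 33 sites it also held group means by the authors, with no account of how these sites were chosen.

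The design fixed before the data were examined named edgeR on counts as the main test. Because counts matched only 8 of 12 libraries, the test it named for normalised values was used instead: limma 3.58.1 (R 4.3.3, trend and robust off) on log2(FPKM + 1), over genes with FPKM of at least 1 in at least 2 libraries (12188 genes). A log2 fold change on this scale understates the change of low genes. The model had a mean for each of the 6 groups and 6 residual degrees of freedom. Contrasts were the mean of both hairpins minus shNC, each hairpin minus shNC, and shM1-2 minus shM1-1, in total RNA, in polysome RNA and in their difference, an interaction taken as translation efficiency, as total RNA normalised polysome RNA in the design of the series. All adjusted p are Benjamini-Hochberg values from limma over all genes tested, or from camera or fry over the lists tested, with a threshold of 0.05. FPKM were not scaled further. Gene length was the median ratio of count to FPKM over libraries with FPKM of at least 1, a definition corrected after length results had been seen.

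Of 30 gene lists fixed before the data were examined (987 members, 940 in the table), 28 were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. The list of mitochondrially encoded mRNAs (0 of 13 in the table) and that of long noncoding RNAs (1 of 30) were not tested. The rule for genes named in the text was fixed too. It takes METTL1, WDR4 and EIF4EBP1, the 10 largest differences upward and downward among genes that passed with the same sign in both hairpins and mean FPKM of at least 2, and up to 4 members of each list with the smallest adjusted p among those that passed. A few genes that the rule takes are not reported here. Where fewer than 5 genes passed in a direction it takes the 5 smallest p. For tRNAs it takes the 6 highest mean scores and the 3 largest and 3 smallest differences. Symbols and coordinates are those of the file, which does not state whether strand was used in counting, so overlapping genes cannot be told apart.

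The tRNA sites were to be the G with the highest mean score in each tRNA. With no base in the file, the position with the highest mean was used, if within the highest 1% of positions. Library medians over sites were compared with an exact two-sided permutation test, and single sites with limma (3 residual degrees of freedom).

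Depth was known for the 8 libraries with counts, at 16712319 to 19808430 expected counts, and was not given in the sources used here for the others. Each step was tested on simulated data. Of 100 genes simulated at a log2 change of 1 among 12188, limma called 70% in total RNA and 70% in polysome RNA, 16% in translation efficiency, 43% for shM1-1 in total RNA and 42% for shM1-2. At a log2 change of 2 it called 100%, 100%, 91%, 96% and 96%. With 200 genes at a log2 change of 1 and none larger, 1% were called in translation efficiency. For shM1-1 in total RNA (13997 genes) edgeR called 14% and 92% at the smaller and larger change and DESeq2 35% and 96%; in translation efficiency (13985 genes) edgeR called 1% and 48% and DESeq2 10% and 78%. Among unchanged genes edgeR called 11 and 10 and DESeq2 31 and 24 in these 2 comparisons, and limma 10, 8, 2, 5 and 7 in the order above. A simulated list shifted by 0.5 was called by each set test. Its genes varied independently, whereas the estimated correlation between genes was 0.924 for cytosolic ribosomal proteins. The simulation thus does not show that fry or camera with an estimated correlation could call such a shift in correlated lists.

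Alternatives fixed before the data were examined were a pseudocount of 0.1, no filter, a mean FPKM of at least 5, fewer libraries in the fit, edgeR 4.0.16 (RLE or upper quartile) and DESeq2 1.42.0 on rounded expected counts of shM1-1 and shNC, the replicate number as a block, each library left out, other shares of tRNA positions, and sites picked in 1 control library. Those added after seeing the data were quantile normalisation, median ratio scaling, removal of each library's length trend, removal of the median of 15 neighbouring genes on each side, a block within each fraction, crossed pairs, leaving out libraries numbered 2, edgeR with TMM, an intensity trend in limma, the authors' sites, loop positions, sites picked in libraries of 1 number and scored in those of the other, sites picked by 1 population among tRNA genes with none of the authors' sites, and subtraction of the median of the other tRNA positions. Where a left-out library leaves a group with 1 library, that library is assumed to vary like the other groups. Python 3.11 and pandas 2.3.3 were used to read the tables.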

Results

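METTL1 and its partner WDR4 form the enzyme that places m7G, a methylated guanosine, on a subset of tRNAs. The study used HOS, a human osteosarcoma cell line, in 3 populations with stable short hairpin RNAs: the control shNC, and shM1-1 and shM1-2, which target METTL1. Polysome profiling, which separates mRNAs bound by several ribosomes from the rest, gave libraries of total RNA and of polysome RNA from each population (n = 2 each, 12 libraries). The sample titles call these fractions input and rnc and do not state how many ribosomes the mRNAs carried. TRAC-seq, in which m7G is reduced and the tRNA is cleaved there with aniline, gave 6 columns of cleavage scores (n = 2 per population). The expected counts of the 8 libraries of shNC and shM1-1 summed to between 16712319 and 19808430, and between 11121 and 11635 genes had an FPKM of at least 1 in each of the 12 libraries. The depth of the shM1-2 and TRAC-seq libraries was not given in the sources used here.

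METTL1 mRNA, measured first because it checks the labels, was lower in both knockdown populations. In total RNA its mean level was 18.2 ± 10.9 FPKM (SD, n = 2) in shNC, 5.3 ± 1.46 FPKM in shM1-1 and 6.26 ± 0.134 FPKM in shM1-2. Across both hairpins METTL1 (chromosome 12, 57768492 to 57772131) fell by 1.39 on the log2(FPKM + 1) scale (SE 0.29, limma adjusted p = 0.0154), with −1.50 in shM1-1 (adjusted p = 0.0238) and −1.28 in shM1-2 (adjusted p = 0.0301). In polysome RNA it fell by 1.35 (SE 0.29, adjusted p = 0.0169), with −1.75 in shM1-1 (adjusted p = 0.0136) and −0.94 in shM1-2 (adjusted p = 0.0852). WDR4 differed by 0.34 in total RNA (SE 0.25, adjusted p = 0.396), and EIF4EBP1, which encodes a repressor of cap-dependent translation, by 0.24 (SE 0.45, adjusted p = 0.749). All of these differences are between shM1 and shNC. The authors' deposited table gave METTL1 a log2 fold change of −1.9 in polysome RNA of shM1-1 (q = 0.000182).

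The METTL1 call in total RNA rested in part on 1 control library, since the shNC replicates stood at 10.5 and 25.9 FPKM. Without shNC total RNA replicate 2 METTL1 was at −0.78 (adjusted p = 0.0684) and WDR4 at 0.86 (adjusted p = 0.0346). The METTL1 call was also lost without shM1-1 total RNA replicate 1 (−1.27, adjusted p = 0.0577) and without shM1-2 total RNA replicate 1 (−1.38, adjusted p = 0.0528). Over all alternatives run, the adjusted p of METTL1 in total RNA lay between 0.00128 and 0.0684, and that of WDR4 between 0.0269 and 0.614. In polysome RNA the METTL1 call was lost without shM1-2 replicate 2 (−1.24, adjusted p = 0.0572), shNC replicate 1 (−1.42, adjusted p = 0.09) or shNC replicate 2 (−1.28, adjusted p = 0.0576), and over all alternatives its adjusted p lay between 0.0018 and 0.184. METTL1 was the 1 of the 2 genes of the m7G writer list, with WDR4, that fell in each fraction, adjusted over all genes or adjusted over the list alone. The METTL1 gene model overlaps those of TSFM, EEF1AKMT3 and CYP27B1, so reads in the shared stretch are uncertain.

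**Figure D1:**
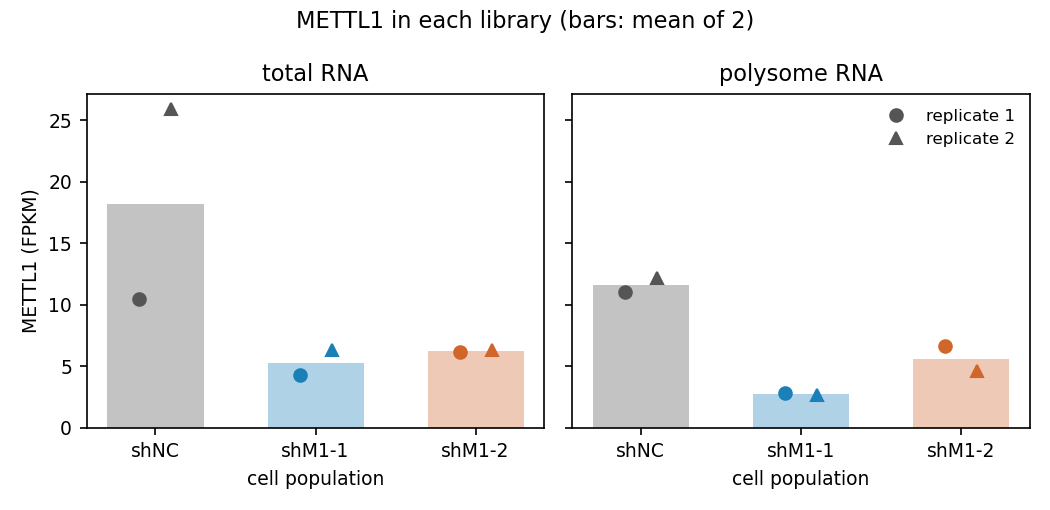
METTL1 level in FPKM (vertical axis, from 0) in each cell population (horizontal axis), in total RNA on the left and polysome RNA on the right. Points are single libraries (circles replicate 1, triangles replicate 2) and bars are means of 2; the shNC total RNA libraries stood at 10.5 and 25.9 FPKM and no knockdown library was above 6.62 FPKM.

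The comparison of total RNA asks which transcripts differed in level with less METTL1. TNC, the matrix glycoprotein tenascin-C, rose by 2.65 (SE 0.38, adjusted p = 0.00268), with 1.26 in shM1-1 and 4.05 in shM1-2. CXCL12, a chemokine, rose by 2.40 (SE 0.16, adjusted p = 0.000219), mostly from shM1-2 (difference between the hairpins 3.63, adjusted p = 5.23e-06), where it reached 18.8 ± 1.02 FPKM (n = 2) against 0.6 ± 0.0141 in shM1-1 and 0.065 ± 0.0636 in shNC. Other large rises were BGN (2.28), ROBO1 (2.06), COL6A3 (2.05), SNAI2 (2.01), CSPG4 (2.00), PTX3 (1.80) and OAF (1.78), with adjusted p from 0.00085 to 0.0219. KISS1, a metastasis suppressor that encodes kisspeptin, fell by 2.98 (SE 0.27, adjusted p = 0.000356), from 200 ± 98.8 FPKM in shNC to 24.1 ± 1.03 in shM1-1 and 22 ± 1.85 in shM1-2. CNN1, the actin-binding protein calponin 1, fell by 2.80 (SE 0.22, adjusted p = 0.000219), from 34 ± 7.63 to 2.87 ± 0.0849 and 5.37 ± 0.0283 FPKM. OLR1 (−2.67), HTRA1 (−2.63), S100A2 (−2.54), IRX2 (−2.50), C5orf38 (−2.33), CST6 (−2.31), NPAS4 (−2.21) and RTP3 (−2.19) followed, with adjusted p from 0.000219 to 0.00685. IRX2 and C5orf38 are direct neighbours on chromosome 5. In the coordinates of the file TNC lies on chromosome 9 (115019575 to 115119364), CXCL12 on chromosome 10 (44282926 to 44385097), KISS1 on chromosome 1 (204190137 to 204196491) and CNN1 on chromosome 19 (11538717 to 11550323).

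Among the gene groups fixed beforehand, the mesenchymal, invasion and adhesion group had the largest share of members that rose. In it 7 of 37 members rose and 2 fell (11 and 2 adjusted over the list alone), and 31 lay above 0. These included TNC, SNAI2 and PLAU, the urokinase protease, at 1.68 (SE 0.18, adjusted p = 0.000748). Of 29 genes of osteoblast differentiation and bone matrix, 3 rose and 4 fell (3 and 5 adjusted over the list alone). Lysyl oxidase (LOX) rose by 1.40 (adjusted p = 0.00606), while the osteoblast transcription factor MSX2 fell by 1.05 (adjusted p = 0.00358), alkaline phosphatase (ALPL) by 0.98 (adjusted p = 0.00401) and the parathyroid hormone receptor PTH1R by 0.79 (adjusted p = 0.00948). Of 23 growth factor receptors and ligands, 2 rose and 2 fell (2 and 3 adjusted over the list alone), among them HBEGF (1.64) and IGF2 (−1.85, with −0.63 in shM1-1 and −3.08 in shM1-2, difference adjusted p = 0.00411). Of 32 G1/S genes, 2 rose and 1 fell, before and after adjustment over the list alone. Cyclin D1 (CCND1) rose by 1.62 (SE 0.16, adjusted p = 0.000566), from 33.1 ± 0.559 FPKM in shNC to 105 ± 5.56 and 102 ± 7.83, CDK6 rose by 0.63 (adjusted p = 0.0411), and CDK4 fell by 0.93 (adjusted p = 0.0372), with −2.24 in shM1-1 and 0.37 in shM1-2 (difference adjusted p = 0.00053).

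EIF3J, a subunit of initiation factor eIF3, rose by 1.22 (SE 0.15, adjusted p = 0.00134), the poly(A)-binding protein PABPC1 by 0.87 (adjusted p = 0.00547) and EIF5 by 0.77 (adjusted p = 0.00816), the 3 of 39 initiation factors that passed (3 adjusted over the list alone). KARS, the lysyl-tRNA synthetase, at 0.70 was the 1 of 23 synthetase genes that rose (1 adjusted over the list alone), and 0 of 22 elongation and termination factors passed under either adjustment. Of 66 other tRNA modification enzymes, 4 rose and 2 fell (3 and 1 adjusted over the list alone), among them the deaminases ADAT2 (0.76) and ADAT1 (0.71), ALKBH1 (0.59) and MOCS3 (−0.60). In the ATF4 group 3 of 35 rose (0 adjusted over the list alone) and 28 lay above 0, with CHAC1, a glutathione-degrading enzyme, at 1.45 (adjusted p = 0.0261). GDF15, a secreted stress cytokine, was at 0.46 over both hairpins, but the hairpins differed by 1.47 (adjusted p = 0.000295). DEPTOR, an inhibitor of mTOR, fell by 0.98 (adjusted p = 0.00265), the 1 of 30 genes of the mTORC1 group that passed (1 adjusted over the list alone). Of 80 cytosolic ribosomal protein genes 2 fell (1 adjusted over the list alone), RPL13A and RPS27, and 4 of 76 mitochondrial ones fell (0 adjusted over the list alone). Ribosomal protein genes have many processed pseudogenes, so their read assignment is uncertain.

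In the respiratory chain group 4 of 56 nuclear-encoded genes fell (3 adjusted over the list alone), among them ATP5F1C, NDUFA9 and NDUFB6, and 52 lay below 0. In cholesterol biosynthesis 4 of 25 fell (5 adjusted over the list alone), with EBP, a sterol isomerase, at −1.42 (SE 0.17, adjusted p = 0.00119), FDPS at −0.85, MVK at −0.81 and PMVK at −0.80. Of 27 genes of doxorubicin transport, target and detoxification, 1 rose and 3 fell under either adjustment. Heme oxygenase (HMOX1) was at 1.38, the carbonyl reductase CBR1, which reduces doxorubicin, at −1.68 (SE 0.17, adjusted p = 0.000525), GSTM3 at −1.02 and the efflux pump ABCG2 at −0.97. HMOX1 and CBR1 moved more in shM1-2 than in shM1-1: CBR1 by −2.86 against −0.51 (adjusted p = 9.24e-05) and HMOX1 by 2.35 against 0.40 (adjusted p = 0.00558). In the p53 group 2 of 24 rose and 2 fell (3 and 2 adjusted over the list alone), among them DDB2 (−0.93), FDXR (−0.83) and PLK3 (1.02). In DNA repair 2 of 38 rose and 1 fell (1 and 1 adjusted over the list alone), among them MDC1 and XRCC4. Caspase 9 (CASP9, −0.98) was the 1 of 30 apoptosis regulators that passed under either adjustment. Of 34 interferon-stimulated genes 2 fell (1 adjusted over the list alone), led by IFI35 (−1.53). Of 20 NF-kB and cytokine genes 2 rose and 2 fell (3 and 2 adjusted over the list alone), among them CSF1 and IL11. Of 33 glycolysis and hypoxia genes 2 rose and 1 fell under either adjustment, with PKM at 0.78. None of 22 unfolded protein response chaperones, 35 G2/M genes or 12 histone genes passed under either adjustment.

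Among marker lists of other cell types few genes were tested. Of 10 epithelial markers 3 fell (1 rose and 4 fell adjusted over the list alone), CLDN3 (−1.58), KRT7 (−0.90) and EPCAM (−0.89). Of 7 blood cell markers 1 fell under either adjustment, CD68 (−0.95). Of 8 fibroblast and endothelial markers 1 rose and 2 fell (1 and 3 adjusted over the list alone), and the hairpins differed in each. THY1 was at 0.93 in shM1-1 and −3.38 in shM1-2 (difference adjusted p = 5.18e-06), LUM at −3.51 and 1.21 (adjusted p = 1.21e-05), and FAP at −0.47 and 1.95 (adjusted p = 0.000155).

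Camera with a preset correlation called 7 lists in total RNA: mesenchymal genes (median 0.39, adjusted p = 2.74e-05), the ATF4 group (0.21, 0.00329), synthetases (0.23, 0.0336), elongation and termination factors (0.26, 0.0373), DNA repair (0.21, 0.0373) and initiation factors (0.06, 0.0385) upward, and the respiratory chain (−0.50, 0.00329) downward. None of the 7 held with an estimated correlation between genes (adjusted p = 0.918 with an estimated correlation for each), nor by fry in the fit without a replicate block (smallest adjusted p = 0.218). The other 21 lists had camera adjusted p from 0.0659 to 0.861. With each library's gene length trend removed, the respiratory chain list was at −0.13 (adjusted p = 0.2) and DNA repair at 0.18 (adjusted p = 0.077). The cytosolic ribosomal protein list turned from −0.20 (adjusted p = 0.354) to 0.19 (adjusted p = 0.0106), and 6 more lists turned sign without a call: mitochondrial ribosomal proteins (to 0.10), histones (0.37), G2/M (0.04), doxorubicin (0.08), interferon (0.03) and blood markers (0.13). In that fit fry called the histone and the NF-kB and cytokine lists upward (adjusted p = 0.037 for each). After quantile normalisation the elongation factor and DNA repair calls were lost (adjusted p = 0.0632 for each) while their medians grew to 0.33 and 0.31, and the medians of the G2/M, doxorubicin, apoptosis, interferon and histone lists changed sign. Median, mean and camera direction differed in sign for the G2/M, histone, doxorubicin and mTORC1 lists, none of which was called.

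Across 12188 genes limma called 512 higher and 1039 lower in total RNA, 1164 in shM1-1 alone (404 higher) and 1909 in shM1-2 alone (681 higher). Fitted with only 1 hairpin and the controls, the latter counts were 292 and 1100. Of the 1551 genes called over both hairpins, 409 also differed between them. The share called higher was 33%, against 47.4% after quantile normalisation, 44.2% after median ratio scaling and 47% with the length trend removed, and the median over all genes was −0.08, against 0.02, 0 and 0. Of the 86 total RNA calls of genes named by the fixed rule, 34 held in all 12 fits that left out 1 library, among them KISS1, CNN1, OLR1, HTRA1, IRX2, CXCL12, TNC, ROBO1, SNAI2, PLAU, CCND1, EIF3J, EBP, CBR1, DEPTOR and THY1. The other 52 did not, among them METTL1, BGN, COL6A3, CSPG4, CDK4, CHAC1, ATP5F1C, NDUFA9 and NDUFB6. The higher count was 173 and 263 without shM1-1 total RNA replicates 1 and 2, 184 and 248 without those of shM1-2, and 263 without shNC total RNA replicate 2. The lower count was 398, 599, 397 and 526 without the same 4 knockdown libraries, and 644 without shNC total RNA replicate 1. For shM1-1 alone the count was 112 and 206 without its total RNA replicates 1 and 2, 725 without either shM1-2 total RNA library and 770 without shNC total RNA replicate 1. For shM1-2 alone it was 507 and 728 without its total RNA replicates 1 and 2.

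Genes that differed were not spread evenly over the genome, a feature chosen after the values were seen. On chromosome 20, 84 of 335 tested genes (25.1%) fell in total RNA and 6 rose, against 1037 of 12153 (8.5%) that fell over all chromosomes. Its median was −0.23 in shM1-1 and −0.53 in shM1-2 in total RNA, and −0.26 and −0.41 in polysome RNA. On chromosome 15, 68 of 402 genes rose and 10 fell, with medians of 0.28 and 0.29. The longest run of shifted neighbouring genes lay on chromosome 20 from 25612935 to 64042781 (225 genes, median −0.62 in shM1-2 and −0.41 in shM1-1). In shM1-2 another run of lower genes lay on chromosome 7 from 93905562 to 102690822 (90 genes, −0.55) and a run of higher genes on chromosome 16 from 31472155 to 66696707 (75 genes, 0.47, against 0.06 in shM1-1). In shM1-1 a run of lower genes lay on chromosome 1 from 152026795 to 156240077 (75 genes, −0.50). A named gene or list member in such a stretch may have been called as part of the shift of its neighbours. Its call then need not concern its gene group. With the median of neighbouring genes removed, 594 of 1038 lower genes in total RNA were still called lower.

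**Figure D2:**
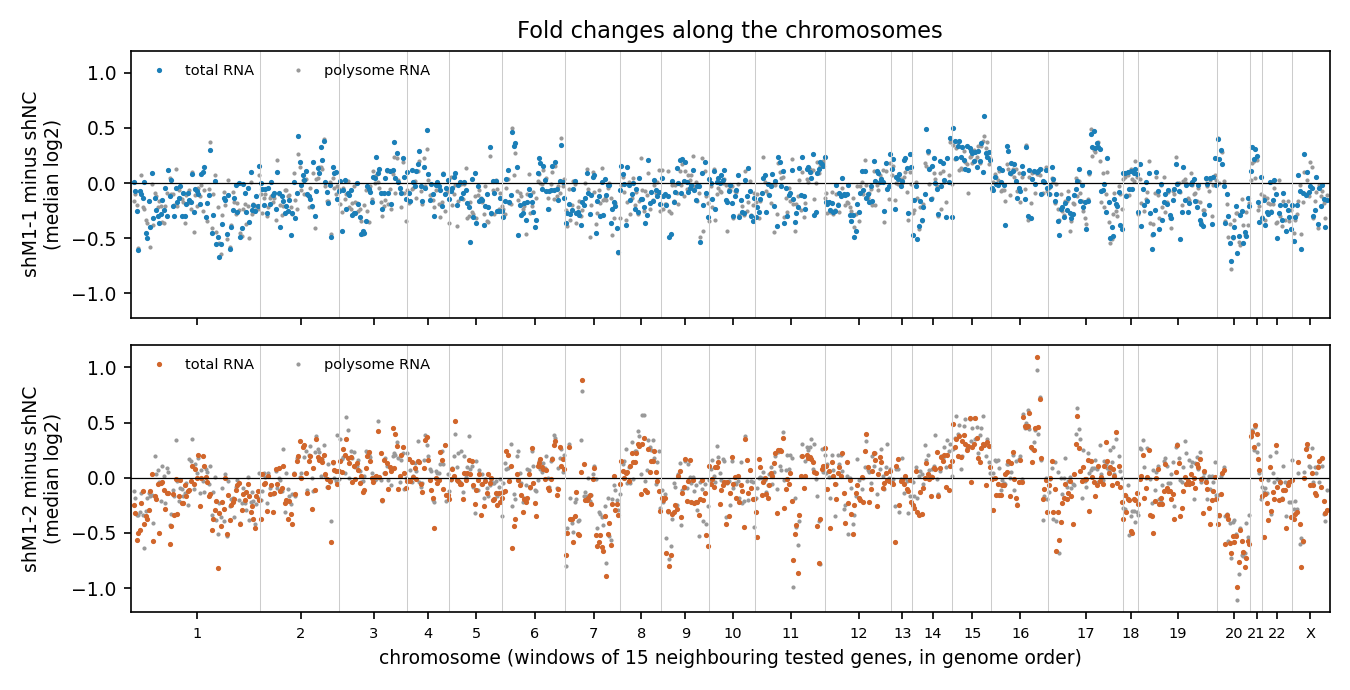
Median log2 difference from shNC over windows of 15 neighbouring genes (vertical axis) along the chromosomes (horizontal axis), shM1-1 above and shM1-2 below, total RNA in colour and polysome RNA in grey. The chromosome 20 run of lower genes has a median of −0.62 in total RNA and −0.54 in polysome RNA of shM1-2.

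The comparison of polysome RNA asks which transcripts differed on translating ribosomes. CNN1, KISS1, HTRA1 and OLR1 were again among the genes that fell most. OLR1, an oxidised LDL receptor, fell by 3.80 (SE 0.37, adjusted p = 0.000383), from 31.8 ± 8.99 FPKM (n = 2) in shNC to 3.65 ± 2.06 in shM1-1 and 0.215 ± 0.0636 in shM1-2. The next were CNN1 (−3.06), KISS1 (−2.87), HTRA1 (−2.79), CPZ (−2.68), IGFBPL1 (−2.54), PCSK1N (−2.54), the chemokine receptor CXCR4 (−2.35), IGF2 (−2.28) and L1CAM (−2.27), with adjusted p from 6.86e-05 to 0.00412. CXCL12 rose by 2.42 (SE 0.16, adjusted p = 6.86e-05), TNC by 2.00, SNAI2 by 1.94, NME1-NME2 by 1.87, FOSL1 by 1.82, HMGA2 by 1.78, CRABP2 by 1.71, CHAC1 by 1.70, OAF by 1.69 and ROBO1 by 1.69, with adjusted p from 0.000532 to 0.0288. NME1-NME2 is a readthrough model that shares reads with NME1 and NME2, so its value is uncertain.

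Of 80 cytosolic ribosomal protein genes 4 rose in polysome RNA (1 adjusted over the list alone), among them RPL4 (0.74, adjusted p = 0.00661), RPS4X (0.69) and RPL6 (0.68). In the mean of both hairpins 75 lay above 0 (median 0.45), but as a list they did not hold with an estimated correlation (adjusted p = 0.844) or by fry (0.513). Of initiation factors 4 of 39 rose (4 adjusted over the list alone), EIF3J (1.23, adjusted p = 0.00108), EIF5 (0.77), PABPC1 (0.56) and EIF4A2 (0.53). EEF1G at 0.44 was the 1 of 22 elongation and termination factors that rose (0 adjusted over the list alone), KARS at 0.78 the 1 of 23 synthetase genes (1 adjusted over the list alone), and MRPL46 and MRPL1 the 2 of 76 mitochondrial ribosomal protein genes (0 adjusted over the list alone). Of 66 other tRNA modification enzymes 2 rose and 2 fell (1 and 0 adjusted over the list alone), ADAT1 (0.94), ADAT2, MOCS3 and ELP4. In the ATF4 group 3 of 35 rose (1 adjusted over the list alone), CHAC1, XPOT and PSAT1. In G1/S 4 of 32 rose (4 adjusted over the list alone), CCND1 (1.47), PCNA (1.04), SKP2 (0.98) and CDC25A (1.35). In the mesenchymal group 6 of 37 rose and 2 fell (6 and 3 adjusted over the list alone), with PLAU at 1.62 and integrin ITGB3 at −1.47, with −0.13 in shM1-1 and −2.80 in shM1-2 (difference adjusted p = 0.000305). In cholesterol biosynthesis 24 of 25 members lay below 0 and 8 fell (11 adjusted over the list alone), led by EBP (−1.79, SE 0.17, adjusted p = 0.000345), MVK (−1.18), NSDHL (−1.08) and FDPS (−0.88).

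Camera with a preset correlation called 10 lists in polysome RNA: cytosolic ribosomal proteins (median 0.45, adjusted p = 3.15e-09), initiation factors (0.23, 0.000323), the ATF4 group (0.29, 0.000457), elongation and termination factors (0.37, 0.000907), G1/S genes (0.19, 0.0202), other tRNA modification enzymes (0.11, 0.0256), mitochondrial ribosomal proteins (0.15, 0.0256), synthetases (0.13, 0.0267) and mesenchymal genes (0.14, 0.0304) upward, and cholesterol biosynthesis (−0.68, 1.58e-05) downward. None of the 10 held: adjusted p = 0.567 with an estimated correlation for initiation factors, elongation factors and the ATF4 group, 0.873 for synthetases and mitochondrial ribosomal proteins, and 0.844 for the other 5. By fry in the fit without a replicate block the smallest adjusted p was 0.0847, and the other 18 lists had camera adjusted p from 0.0519 to 0.806. After quantile normalisation the synthetase (median 0.19, adjusted p = 0.0849), G1/S (0.28, 0.058) and mesenchymal (0.11, 0.136) calls were lost and the epithelial list was called (0.0429), and with the length trend removed the mesenchymal call was lost (0.0697) while its median grew from 0.14 to 0.21. By fry the NF-kB and cytokine list was called after quantile normalisation (0.0182) and cytosolic ribosomal proteins with the length trend removed (0.013). Of lists not called, median, mean and direction differed in sign for the p53, doxorubicin, apoptosis, interferon and glycolysis groups. The fibroblast and endothelial, epithelial and blood marker lists had medians of −0.50, −0.69 and −0.28, with CDH5 (−2.16), CLDN3 (−1.65), CD68 and CD14 among those that fell.

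Across 12188 genes limma called 446 higher and 1042 lower in polysome RNA, 1003 in shM1-1 alone (258 higher) and 2031 in shM1-2 alone (780 higher). Fitted with only 1 hairpin and the controls, these counts fell to 0 for shM1-1 and 688 for shM1-2. The share called higher was 30%, against 43.8% after quantile normalisation, 34.1% after median ratio scaling and 41.7% with the length trend removed. Of the 85 named polysome calls 32 held in all 12 fits that left out 1 library, among them OLR1, CNN1, KISS1, HTRA1, CXCL12, SNAI2, HMGA2, PLAU, CCND1, EIF3J, EBP, ALPL and INSR, and 53 did not, among them METTL1, TNC, FOSL1, CHAC1, PCNA, RPL4, RPS4X and RPL6. The higher count was 226 without shM1-1 polysome RNA replicate 1, 211 and 184 without shM1-2 polysome RNA replicates 1 and 2, 100 without shNC polysome RNA replicate 1, 272 without either shM1-1 total RNA library and 271 without either shM1-2 total RNA library. The lower count was 634 and 684 without shM1-1 polysome RNA replicates 1 and 2, 664 and 521 without those of shM1-2, and 286 without shNC polysome RNA replicate 1. For shM1-1 alone the count was 211 and 328 without its polysome RNA replicates 1 and 2, 268 and 1738 without those of shNC, 608 without any 1 knockdown total RNA library and 1508 without either shNC total RNA library. For shM1-2 alone it was 905 and 673 without its polysome RNA replicates 1 and 2, and 1233 without shNC polysome RNA replicate 1. Polysome libraries numbered 2 had 18.4% to 21.4% of their FPKM in genes under 1000 bases, against 27% to 30.1% in those numbered 1. Without the 3 polysome libraries numbered 2 the counts were 83 higher and 373 lower.

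In the authors' deposited table, q was under 0.05 for 739 genes in polysome RNA of shM1-1 against shNC. Of these 691 were tested here and 538 were also limma calls, and fold changes correlated at r = 0.9 across genes, which are not independent replicates.

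The design also asks whether both hairpins act alike. Across genes, which are not independent replicates, the fold changes of shM1-1 and shM1-2 correlated at r = 0.44 (rho = 0.47) in total RNA and r = 0.42 (rho = 0.43) in polysome RNA. Both share the same control libraries, and 100 simulations of unchanged groups against shared controls gave 0.50 (rho = 0.47) and 0.50 (rho = 0.48). The covariance was 0.142 against a simulated 0.034 in total RNA and 0.13 against 0.034 in polysome RNA, a surplus of 0.107 and 0.095. For the polysome to total RNA ratio taken up below the correlation was 0.79 (simulated 0.50), and the covariance was 0.068 against a simulated 0.069 (surplus −0.001). The simulations drew noise independently for each group. Deviations of same-numbered libraries correlated at 0.46 to 0.61 across total RNA and 0.61 to 0.76 across polysome RNA. Such shared deviations cancel between populations, so the simulated covariances may be too large. For the ratio they cannot decide whether the hairpins agree beyond noise. Both hairpins called 120 genes higher and 324 lower in total RNA, where independent lists would share 22.6 and 76.6, and 80 and 321 in polysome RNA, where independent lists would share 16.5 and 76.5. The 2 controls per fraction were not split between the hairpins, so part of these overlaps may come from them. The hairpins also differed from each other at 1704 genes in total RNA (880 higher in shM1-2, 824 lower) and 1902 in polysome RNA (1120 higher, 782 lower). Without shM1-1 total RNA replicates 1 and 2 and those of shM1-2 in turn the total RNA count was 619, 578, 558 and 578, and without the matching polysome libraries the polysome RNA count was 1099, 887, 806 and 729.

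The ratio of polysome to total RNA, termed translation efficiency here and tested as an interaction, asks whether ribosome loading changed beyond transcript level. As single genes, none passed: limma called 0 of 12188 across both hairpins, with 140 at an unadjusted p under 0.05, and 0 in shM1-1 (51), in shM1-2 (155) and between them (42). Well calibrated p-values would put a share of 0.05 of unchanged genes under 0.05. Each of these counts is below that share, so the p-values ran large. The fit without a replicate block may count deviations shared by same-numbered libraries as spread, although they cancel in this ratio. For shM1-1, edgeR on rounded expected counts called 0 genes and DESeq2 called 1. The smallest p upward belonged to POLR2J2 (1.07, SE 0.27), GSTA4 (0.96), UQCRHL (1.33), NME1-NME2 (1.68) and NEDD8-MDP1 (1.07), and downward to EFNA5 (−0.80, SE 0.19), GOLGA4 (−0.85), CYP2S1 (−0.74), C4BPB (−0.56) and TNFSF9 (−0.59), each with an adjusted p of 1. POLR2J2, UQCRHL and the readthrough models share reads with near-identical genes and are uncertain. METTL1 was at 0.04 (SE 0.42), WDR4 at −0.03 (SE 0.36) and EIF4EBP1 at 0.36 (SE 0.63), each with an adjusted p of 1, and METTL1 lay between −0.19 and −0.01 under 3 other scalings and a smaller pseudocount. Of 200 simulated doublings or halvings at the measured spread, 1% were called.

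The gene lists in translation efficiency are described by their medians, since no list called by camera with a preset correlation held with an estimated one (adjusted p = 0.713 to 0.742). All 80 cytosolic ribosomal protein genes lay above 0 (median 0.66, 0.62 in shM1-1 and 0.71 in shM1-2), as did 73 of 76 mitochondrial ones (median 0.37) and 48 of 56 respiratory chain genes (median 0.34). Downward, 26 of 29 bone matrix genes (median −0.44), 23 of 25 cholesterol biosynthesis genes (−0.37), 21 of 22 unfolded protein response chaperones (−0.31), 20 of 23 growth factor receptors and ligands (−0.30), 30 of 37 mesenchymal genes (−0.22) and 6 of 8 fibroblast and endothelial markers (−0.22) lay below 0. No member of any list passed alone, over all genes or adjusted over the list alone. Not every list differed with both replicate numbers. The cholesterol list stood in polysome minus total RNA at 0.13 (shNC), 0.12 (shM1-1) and 0.13 (shM1-2) in libraries numbered 1, and at 1.07, 0.54 and 0.22 in those numbered 2, so its change came from the latter. By camera with a preset correlation the adjusted p was 2.62e-32 for cytosolic ribosomal proteins, 2.64e-12 for mitochondrial ones, 1.83e-05 for the respiratory chain and for growth factor receptors, 4.82e-08 for bone matrix, 1.3e-05 for cholesterol, 1.66e-05 for chaperones, 4.92e-05 for mesenchymal genes and 0.0488 for fibroblast markers. G2/M genes (median 0.16, adjusted p = 0.0381), initiation factors (0.17, 0.0452) and other tRNA modification enzymes (0.10, 0.0479) were called upward too, 12 lists in all. None of the 12 held: adjusted p = 0.713 with an estimated correlation for cytosolic ribosomal proteins, chaperones, bone matrix, mesenchymal genes and growth factor receptors, and adjusted p = 0.742 for the other 7. The smallest fry adjusted p in the fit without a replicate block was 0.913, and the other 16 lists had camera adjusted p from 0.0548 to 0.975. Median, mean and direction differed in sign for the synthetase, mTORC1 and DNA repair lists.

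Translation efficiency fold changes fell with gene length across genes (Spearman −0.50), while those of total RNA rose with it (0.38) and those of polysome RNA did so little (0.07). With each library's length trend removed, camera with a preset correlation still called cytosolic ribosomal proteins (median 0.31, adjusted p = 3.1e-29), mitochondrial ones (0.11, adjusted p = 9.79e-05) and bone matrix (−0.41, adjusted p = 7.59e-08). It also called chaperones, mesenchymal genes, growth factor receptors, cholesterol and fibroblast markers. The respiratory chain (0.04, adjusted p = 0.423), initiation factor (0, 0.545), G2/M (0.09, 0.082) and tRNA modification (0.05, 0.0752) lists were not called. Without single libraries the corrected median ran from 0.21 to 0.42 for cytosolic and from 0 to 0.25 for mitochondrial ribosomal proteins. In the main fit no such call held with an estimated correlation. The 6 downward lists kept a median share of 1.1 of their medians and the 6 upward ones 0.38. After quantile normalisation the initiation factor (median 0.04, adjusted p = 0.443) and G2/M (0.08, 0.165) calls were lost and the histone list was called (0.0488), and none of the 12 lists changed sign under these scalings.

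**Figure D3:**
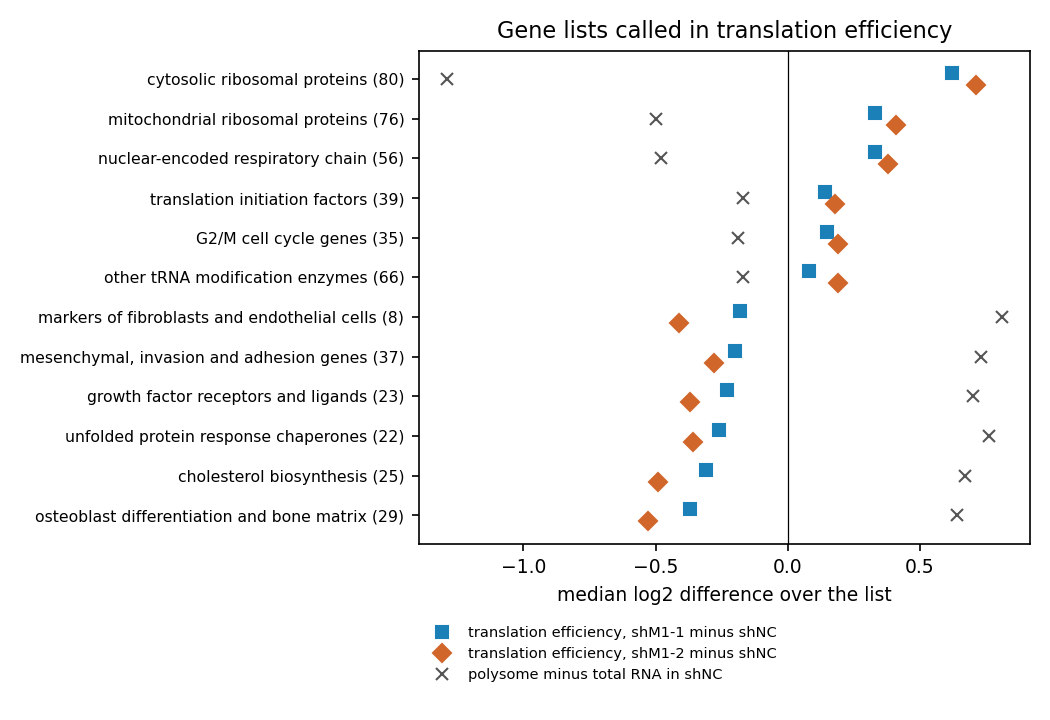
Median log2 difference over each gene list called in translation efficiency (horizontal axis; number of genes tested in brackets) for shM1-1 minus shNC (squares) and shM1-2 minus shNC (diamonds), with polysome minus total RNA in shNC (crosses). Both hairpin values subtract the shNC values shown as crosses, so the sides on which they lie are in part set by construction, as for cytosolic ribosomal proteins at 0.62, 0.71 and −1.29.

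In shNC, cytosolic ribosomal protein mRNAs were lower in polysome than in total RNA (median −1.29, 51 of 80 lower, 74 adjusted over the list alone), and 9 of 22 chaperones were higher (median 0.76, 16 adjusted over the list alone). Camera with a preset correlation gave the 2 lists adjusted p of 8.59e-25 and 2.06e-06, but neither held: adjusted p = 0.816 with an estimated correlation and 0.101 by fry, for each. Translation efficiency subtracts these same libraries, so its opposite sign is not a separate finding. Of 12188 genes limma called 984 higher and 474 lower in polysome RNA. The call depended on single libraries: 4 genes passed without shNC polysome RNA replicate 2, 21 without shNC total RNA replicate 2 and 3322 without shNC total RNA replicate 1. Other left-out libraries lowered it to 711 (either shM1-1 total RNA library), 837 (either shM1-2 polysome RNA library) and 596 (either shM1-2 total RNA library). Without the 3 polysome libraries numbered 2 the count was 0, with 1 shNC polysome library left, and edgeR with both called 7. The authors' deposited table gave q under 0.05 to 580 genes for this comparison, and 512 of the 574 tested here were limma calls. Between shM1 and shNC, 993 of the 1551 genes called in total RNA and of the 1488 called in polysome RNA were called in both with the same sign, and 0 with opposite signs.

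TRAC-seq asks which tRNA positions carry m7G and whether they lose it with less METTL1. Of 27547 positions in 626 tRNA genes, the 1% with the highest mean score over all 6 libraries were taken, 234 sites in 42 tRNA types after keeping the highest in each tRNA. Of these 137 lay at positions 46 to 49 of the tRNA gene, taken here as the variable loop, where METTL1 methylates. The rest lay elsewhere, among them 20 at position 78 and 13 at position 69. With no base given, the picked sites, above all those elsewhere, need not be m7G. The highest mean scores were those of LeuAAG chr16.trna17 at position 26 (5.21), CysGCA chr17.trna27 at position 47 (5.00), ThrTGT chr14.trna22 at position 25 (4.86), GluTTC chr14.trna15 at position 55 (4.74), MetCAT chr8.trna8 at position 48 (4.66) and LeuCAA chr1.trna1 at position 57 (4.54). AlaAGC had the most sites (19, mean score 3.78), followed by ValCAC (13) and PheGAA (12). The tRNA genes of 1 type are near-identical, so reads and scores of single genes are uncertain.

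The median score over the 234 sites was lowest in shNC. It was 3.34 ± 0.09 (SD of library medians, n = 2) in shNC, 3.44 ± 0.07 in shM1-1 and 3.71 ± 0.21 in shM1-2, while the 11176 other positions had medians from −0.08 to 0.21. The difference of 0.24 had an exact two-sided permutation p of 0.267 over the 15 splits of 6 libraries, which allow no p under 0.0667. Knockdown libraries were 4 of the 6 that picked the sites. With sites picked in the libraries of 1 number and scored in those of the other, the difference was 0.20 (picked in those numbered 1) and 0.15. Only 1 shNC library was scored in each, too few for the permutation test to reach the threshold, so these values decide nothing by themselves. Limma called 0 sites, with 14 at an unadjusted p under 0.05 (171 sites above 0, 63 below, 3 residual degrees of freedom), and 0 for shM1-1 (16), shM1-2 (24) and between the hairpins (35). The largest differences were those of ValAAC chr5.trna7 at position 70 (2.14), IleGAT chrX.trna5 at position 49 (2.10) and IleGAT chrX.trna7 at position 49 (2.00), and the lowest those of ArgTCT chr1.trna90 at position 49 (−1.48, from 4.46 ± 0.52 in shNC to 3.03 ± 0.18 and 2.95 ± 0.04), ValAAC chr6.trna37 at position 69 (−1.22) and AlaAGC chr6.trna22 at position 48 (−1.14), with adjusted p from 0.129 to 0.665. In simulated scores with a drop of 1 at 200 sites, 31% of them were called. At sites picked in shNC replicate 1 alone (230 sites) the difference, with that library left out of the control mean, was −0.11. This too left 1 shNC library, too few for the permutation test to reach the threshold.

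The authors gave group means for 33 sites, whose choice is not explained in the sources used here. At these 27 of 33 sites were lower in the mean of both hairpins, 17 with each hairpin, and limma called 2 lower. Their median was 4.38 in shNC, 4.03 in shM1-1 and 4.18 in shM1-2, a difference of −0.28 (exact permutation p = 0.133). All 33 ranked among the 50 highest of 27547 positions by shNC mean. Of the 33 sites 22 lay at positions 46 to 49. The largest falls lay outside these, at position 71. CysGCA chr17.trna25 went from 4.34 in shNC to 1.51 in shM1-1 and 1.72 in shM1-2, and GlnTTG chr6.trna135 from 4.19 to 1.72 and 2.00. With no base given, these sites need not be m7G.

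**Figure D4:**
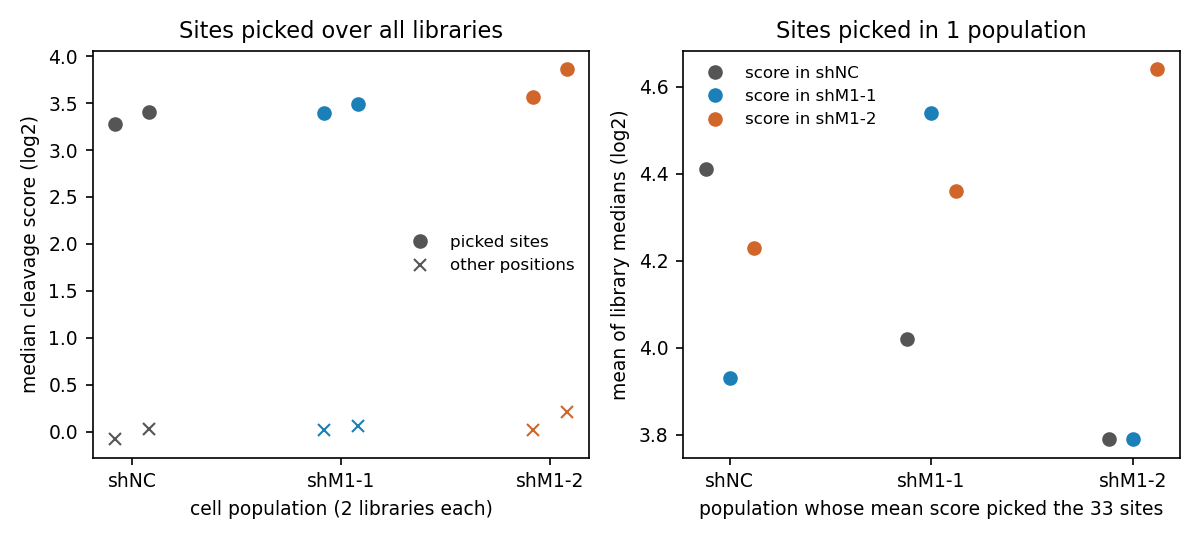
Left, median cleavage score (log2) over the 234 picked sites (circles) and 11176 other positions (crosses) in each of 6 libraries; site medians ran from 3.28 to 3.86 and shNC held the lowest. Right, mean of library medians at 33 sites picked by the mean score of 1 population (horizontal axis); sites are scored in the libraries that picked them, which favours the picking population, as 4.41 in shNC against 3.93 and 4.23 (27 of those 33 sites were the authors'). Among tRNA genes with none of the authors' sites those picked by shNC scored 3.88 in shNC, 3.62 in shM1-1 and 3.91 in shM1-2.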

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

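The tests of chromosome stretches, of length trends in the downward and upward lists apart, of the separation of the fractions, of a library-wide shift of scores, of sites scored in other libraries than those that picked them, and of sites picked by a high control score were chosen only after the result was seen; the others were fixed before. The hairpins differed from each other at 1704 genes in total RNA and 1902 in polysome RNA by limma's test of the difference itself. They were called in opposite directions against shNC at 42 genes in total RNA and 47 in polysome RNA, THY1 and LUM among them.

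Fold changes were shared along chromosome stretches. Between the hairpins in total RNA, the variance of medians over 15 neighbouring genes was 2.48 times that with shuffled gene order (permutation p = 0.002, the smallest that 500 shuffles of gene order allow), which is consistent with gain or loss of chromosome stretches between the cell populations, a candidate source that no DNA measurement here tests. A length trend as the cause is argued against: with length trends removed, chromosome 20 still stood −0.45 from all genes in shM1-2. Differences between replicate libraries are argued against for chromosome 20, which shifted by at most 0.08 between replicates of any of 6 groups. A technical difference common to both libraries of a population cannot be told apart from the population by this test. The first test tried for library differences, the same variance ratio between replicates, gave 1.28 to 1.84 and decided nothing. Each replicate comparison also had a permutation p of 0.002, so that p does not separate populations from libraries. In total RNA the ratio was 1.93 for shM1-1 minus shNC against 1.79 between the shM1-1 replicates. For shM1-2 these were 2.7 and 1.32. Neighbour sharing elsewhere thus stays partly open to library differences.

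Gene lists but no single gene passed in translation efficiency, and without a replicate block the lists passed only by camera with a preset correlation (adjusted p = 0.713 to 0.742 with an estimated correlation, smallest fry adjusted p 0.913). At the spread measured without a replicate block, 1% of simulated doublings or halvings were called, so single genes could have been missed. That spread may include deviations shared by same-numbered libraries, which cancel in differences of translation efficiency. With a replicate block within fraction, which takes up such deviations, none of the genes named in translation efficiency gained a call (METTL1 limma adjusted p = 0.972). The share of simulated changes called was not measured for that fit. The median ratio of polysome to total RNA change over genes called in total RNA was 0.87, so most of the change was shared by the fractions. Length trends as the cause of all the lists are argued against. After their removal camera with a preset correlation still called 8, exactly on the bound set beforehand. The downward lists kept a median share of 1.1 of their medians (0.87 to 1.25 without single libraries). Single lists varied more: without single libraries the corrected median ran from −0.92 to 0.09 for cholesterol and from −0.54 to 0.05 for fibroblast markers. The other downward lists stayed negative. For the upward lists, which kept 0.38 (0.12 to 1.08) while 4 calls ended, length and a change in loading cannot be told apart. A weaker separation of polysome from total RNA in the knockdown populations may account for the lists: outside the lists the shNC slope was 1.22 times that between knockdowns, barely over the bound of 1.2, and a biological change in loading with the hairpins stays open, untested.

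Cleavage scores at the picked tRNA sites were not lower in the knockdown populations, which held 4 of the 6 libraries that picked them. After subtracting the median of the other positions the difference at the picked sites was 0.14. It was 0.10 and 0.05 where the sites were picked in libraries of 1 number and scored in those of the other. Knockdown libraries took part in each of these picks, so a site that lost much score could miss the threshold (a mean of 2.98 over all libraries). These values therefore cannot decide whether a library-wide shift hid a loss. At sites picked in shNC replicate 1, shNC replicate 2 lay only 0.11 above the mean of the shM1 libraries, so a lower score there may be regression to the mean. Choice by a high control score cannot be told apart from a loss for the −0.28 at the authors' 33 sites: as many sites picked by their shNC mean among other tRNA genes differed by −0.11, between the bounds. Remaining METTL1 activity stays open, untested.

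Values not weighed further follow. The control libraries numbered 2 stood at a median share of 0.24 (total RNA) and 0.31 (polysome RNA) of the way to shM1-1, and 0.07 and 0.18 of the way to shM1-2. Replicates correlated (Spearman) at 0.962 (total RNA) and 0.963 (polysome RNA) in shNC, against 0.977 to 0.99 in the knockdown groups. The shNC and shM1-1 libraries numbered 2 correlated at 0.968 in polysome RNA and 0.957 in total RNA. Every difference from shNC rests on these control libraries. At positions 46 to 49 alone the cleavage difference was 0.27.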

How the results depend on the processing

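Fits chosen only after the result was seen are named as such in the processing account, and the tests with a block within fraction, other scalings, libraries numbered 2 left out, the authors' sites, sites scored in other libraries than those that picked them and neighbouring genes belong to them. The cause was not tested for any change below, except that fewer genes or libraries were tested where a filter or a left-out library says so. Of 4553 comparisons of 199 named values with an alternative, 3778 kept direction and side of the threshold, 747 lost their call, 2 gained it and 26 changed sign. With mean FPKM of at least 5 (8299 genes), counts in total RNA were 294 higher, 559 lower, 641 (shM1-1), 1007 (shM1-2) and 911 (between), and in polysome RNA 243, 576, 537, 1135 and 1081. With only the libraries of the fraction, polysome counts were 181 higher, 515 lower and 1125 between; with only 1 hairpin and the controls they were 292 and 1100 in total RNA and 0 and 688 in polysome RNA. For shM1-1, edgeR called 525 and 422 genes with RLE, 537 and 445 with upper quartile and 528 and 429 with TMM (total, polysome), and DESeq2 called 1 in translation efficiency. Quantile normalisation gave 694 higher in polysome RNA. Removing length trends gave 862 higher in total RNA, 878 higher in polysome RNA, 1558 for shM1-1 in polysome RNA and a correlation between hairpins of 0.39. METTL1 in translation efficiency changed sign to −0.03 (pseudocount 0.1), −0.03 (quantile), −0.01 (median ratio) and −0.19 (length). With the median of neighbouring genes removed 692 were lower in total RNA. Estimated correlation left 0 lists in total RNA, 0 in polysome RNA and 0 in translation efficiency.

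The replicate numbers are only 2 and the labels name no batch. Deviations of same-numbered libraries correlated at 0.46 to 0.61 across total RNA and 0.61 to 0.76 across polysome RNA, and between the fractions of 1 population at −0.46 (shM1-1), −0.40 (shM1-2) and 0.09 (shNC). The replicate block over all libraries gave 521 higher and 1074 lower in total RNA, 461 and 1112 in polysome RNA, 0 in translation efficiency and METTL1 at −1.39 (adjusted p = 0.0168). The replicate block within fraction gave 1699 higher, 2920 lower, 4391, 4765 and 4197 in total RNA, 1573, 2554, 3680, 4728 and 4455 in polysome RNA, and 5028 for polysome minus total RNA in shNC. With it fry called the mesenchymal (adjusted p = 0.0223) and respiratory chain lists (0.00322) in total RNA, none in polysome RNA (smallest 0.0625) and the respiratory chain in translation efficiency (0.0477). Camera newly called cytosolic (0.0161) and mitochondrial ribosomal proteins (0.0157), chaperones (0.0344) and bone matrix (0.0109) in total RNA, DNA repair (0.0281) and epithelial markers (0.0499) in polysome RNA and histones (0.0436) in translation efficiency. There it lost tRNA modification (0.0509), initiation factors (0.153), G2/M (0.0592) and fibroblast markers (0.0744). Crossed pairs gave 0 genes in translation efficiency. Without the 3 polysome libraries numbered 2 polysome counts were 83 higher, 373 lower, 172, 602 and 333, shNC polysome minus total 0 and the correlation 0.54. Without the 2 control libraries numbered 2 counts were 2154 (shM1-1) and 2749 (between) in total RNA, 728 higher, 1919 lower, 2769 and 3043 in polysome RNA and 3 in shNC, correlations were 0.52 and 0.57, METTL1 was at −0.78 (adjusted p = 0.0544), and METTL1 and EIF4EBP1 in translation efficiency changed sign to −0.50 and −0.60.

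Leaving out each library in turn gave in total RNA 173 to 619 higher, 397 to 1383 lower, 112 to 1652 for shM1-1, 507 to 2237 for shM1-2 and 558 to 2108 between them. In polysome RNA it gave 100 to 614, 286 to 1383, 211 to 1738, 673 to 2527 and 729 to 2413, in translation efficiency 0 to 1 for shM1-2 (limma, 1 without shNC total RNA replicate 2) and 0 elsewhere, and 4 to 3322 for shNC. METTL1 ran from −2 to −0.78, WDR4 from −0.18 to 0.86 and EIF4EBP1 from −0.41 to 0.90. In translation efficiency they ran from −0.57 to 0.66, −0.55 to 0.48 and −0.30 to 1.02. Correlations between hairpins ran from 0.38 to 0.56 in total RNA, 0.35 to 0.57 in polysome RNA and 0.43 to 0.92 in translation efficiency.

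For tRNAs, the top 2% and 0.5% of positions gave 365 and 130 sites. The cleavage difference changed sign at sites picked in shNC replicate 1 alone (−0.11) and at the authors' sites (−0.28, 2 sites called). It ran from 0.14 to 0.30 without single libraries and was 0.24 with a replicate block, with 0 sites called by limma. ThrTGT at position 25 changed sign to −0.04 with other positions subtracted. Without single libraries CysGCA at position 47 ran from −0.72 to 0, ThrTGT at position 25 from −0.41 to 0.54, GluTTC at position 55 from −0.06 to 1.14 and MetCAT at position 48 from −0.15 to 0.12. Motif picking, codon content and count tests for shM1-2, both hairpins and between them were not run, as the base, coding sequences and matched counts were not used here. Depth was known for 8 libraries only, so what it limits was not measured, and with 2 libraries per group 1% of simulated doublings or halvings were called in translation efficiency. With sites picked in libraries numbered 1 and scored in the others the cleavage difference was 0.20 (0.10 with other positions subtracted), and with those numbered 2 it was 0.15 (0.05).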

Other observations

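The genes next to METTL1 were examined after their values were seen, so all tests here were chosen only after the result was seen. CDK4, a G1 cyclin-dependent kinase, lies on chromosome 12 (57745023 to 57752447) with its end 16045 bases from the start of METTL1. It was at −2.24 in total RNA of shM1-1 (SE 0.29, limma adjusted p = 0.00236) and −1.83 in polysome RNA (adjusted p = 0.00584). In shM1-2 it was at 0.37 (adjusted p = 0.428) and 0.74 (adjusted p = 0.11), and the difference between the hairpins was 2.60 in total RNA (adjusted p = 0.00053). TSPAN31, whose gene model overlaps CDK4, was at −1.39 in shM1-1 (adjusted p = 0.0494) and −1.42 in shM1-2 (adjusted p = 0.0285) in polysome RNA, and at −1.15 (adjusted p = 0.0804) and −1.03 (adjusted p = 0.0912) in total RNA. Of the 10 genes within 100000 bases, those other than METTL1 had a median of −0.37 in shM1-1 and −0.25 in shM1-2 in total RNA. Reads shared by the overlapping models of CDK4, TSPAN31 and AGAP2 cannot be assigned to strands.

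With the median of neighbouring genes removed, 594 of 1038 lower genes and 346 of 512 higher genes in total RNA were called in both fits, and 664 of 1044 and 277 of 447 in polysome RNA.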
